A study of Homo sapiens with 2 samples.

How the data were processed

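RNA sequencing was performed on FaDu cells, an established line derived from a human squamous carcinoma of the hypopharynx. Per the labels' protocols, stable cells were made by lentiviral transduction with either a Snail construct or an empty vector, and total RNA was extracted with TRIzol and taken through an Illumina library preparation. The series holds 2 samples in 2 groups, 1 Snail and 1 vector control. The values analysed here come from 1 library, that of the Snail cells. Values of the vector control were not analysed here, so no fold change, test, p-value or count of changed genes between the groups was computed, and all statements describe the Snail library alone.

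The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, 1 value per row, each row carrying a gene symbol, per the file headers. TopHat2 2.0.8, Cufflinks 2.1.1, Cuffdiff and the genome build hg19 are named in the submitters' processing notes, without the role of each. The gene annotation and any filter are not given in the sources used here. FPKM carries no read counts, and with 1 library and no record of the lengths used by the authors the number of fragments behind a value could not be recovered. The depth is therefore unknown and no counting interval or detection floor is given. A value of 0 is described as listed at 0.

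The table had 19477 rows and 17629 gene symbols. Of the 996 symbols found on more than 1 row, 718 had a single nonzero row, 34 had several and 244 were at 0 on every row. Rows of a repeated symbol were summed. In 541 places, neighbouring rows with different symbols held exactly the same nonzero FPKM, which covered 1174 symbols or 8.09% of those above 0. The 633 neighbouring pairs of rows with such a value compare with at most 1 in 100 shuffled row orders. A few of these symbols differ only in letter case, as C20ORF141 and C20orf141 do, and were counted separately. Where the symbols name different genes, a value of this kind cannot be assigned to one of them, and this is stated beside each named gene that has one. Genes with near-identical copies (the KRT6 genes, ribosomal protein genes, EEF1A1, ACTG1, NPM1 and histone genes) are uncertain in the same way, since the handling of reads that match several copies is not given in the sources used here.

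Gene levels were expressed as log2(FPKM + 1), and a gene was counted as detected at 1 FPKM or more. Before the data were examined, 29 gene lists with 356 entries were fixed, covering epithelial, keratin, squamous, mesenchymal, matrix, signalling, proliferation and stress genes as well as markers of other cell types. For 335 entries a value was available under the current or an older symbol. The list of mitochondrially encoded genes had none, and it was not analysed here. Other entries not analysed here include TWIST2, KRT17, TNF, PKM, RPS18 and PECAM1. Each list's median was placed among the medians of 10000 random lists of the same size drawn from all symbols, and lists above the 97.5th or below the 2.5th percentile are called above or below random lists. These percentiles describe 1 library and are not p-values, because genes are not replicates. On simulated libraries of 17629 genes, random lists of 14 genes were drawn from all symbols and their values moved upward by a known amount. Without a shift, 2 of 30 lists fell outside these limits. A shift of 1 log2 unit placed 4 of 30 above the upper limit, a shift of 2 placed 12 of 30 and a shift of 4 placed 30 of 30. A list of 14 genes within the limits can therefore still hold an upward shift of 2 log2 units or less. Downward shifts and lists of other sizes were not simulated.

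The genes named were set by a rule fixed before the data were examined: SNAI1, the 10 genes with the highest FPKM, and in each list the 3 highest members and, in lists with 5 or more measured members, the lowest. Where several members were at 0, the first in the list was taken. Genes named beyond this rule were chosen after their values were seen: CDH1, VIM, CDH2, FN1, ZEB1, ZEB2 and TWIST1, the genes next to SMAD4 and CTTN, AHNAK, genes that share a value with a named gene, and the receptor and cancer-associated genes of the closing observations (EGFR, ERBB2, ERBB3, MET, CDKN2A, NOTCH1, FAT1 and PIK3CA). The order of genes along chromosomes was taken from GENCODE release 29, in which 16402 of the symbols were found. With older symbols from a RefSeq table, 17188 were placed. That annotation is on a later build than hg19, so it was used only to find neighbours, and no coordinates are given.

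Alternatives fixed beforehand were detection thresholds of 0.1, 0.5 and 5 FPKM, pseudocounts of 0.1 and 0.5, values rescaled to sum to 1000000, genes under 1 FPKM left out, the highest row kept for a repeated symbol, and ribosomal protein, histone and mitochondrial genes left out of the sum. Leaving out symbols with a shared value, and counting a shared value once, were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.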

Results

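The study set FaDu head-and-neck squamous carcinoma cells that stably carried a Snail construct beside cells that carried the empty vector, to describe the transcriptome under Snail, the zinc-finger repressor encoded by SNAI1. Gene levels were examined in the Snail library (1 library, no replicates), and the values below therefore have no replicate error and are compared within this library only. The values of the vector control were not analysed here, so none of the levels below can be ascribed to Snail. Of 17629 gene symbols, 10923 (62.0%) stood at 1 FPKM or more, 1056 at 100 FPKM or more, and 3115 (17.7%) were listed at 0. The median was 4.79 FPKM over all symbols and 17.1 FPKM over those at 1 FPKM or more. The number of fragments sequenced is unknown.

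SNAI1 itself was measured at 93.8 FPKM, a level higher than 93.6% of all symbols. It was the highest of the 10 measured EMT transcription factors, the regulators associated with epithelial-mesenchymal transition. TCF3, which encodes the E2A proteins, followed at 71.9 FPKM and SNAI2, the gene of the related repressor Slug, at 18.7 FPKM. SNAI1 was thus 5.01-fold above SNAI2. TWIST1 stood at 4.70 FPKM and ZEB1 at 0.822 FPKM, 19.9-fold and 114-fold below SNAI1, and ZEB2 was also under 1 FPKM. The lowest member was PRRX1 at 0.0570 FPKM. Of these 10 genes, 5 were under 1 FPKM, and the median of the list (2.76 FPKM) lay at the 32.0th percentile of random lists, within their range. The 5 members at 1 FPKM or more lay at the 55.1st percentile when lower symbols were left out. Gene symbol values do not separate transcripts of the construct from those of the endogenous gene.

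**Figure D1:**
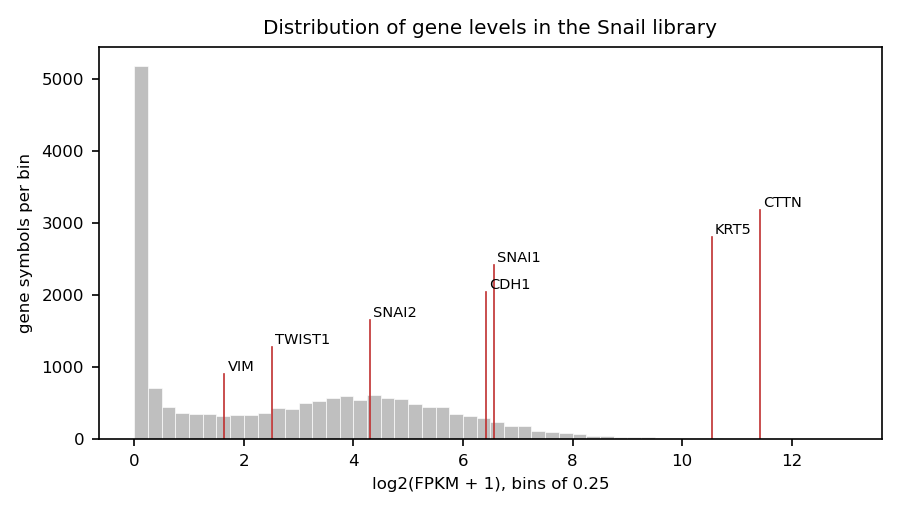
Histogram of log2(FPKM + 1) for the 17629 gene symbols of the Snail library, in bins of 0.25 (vertical axis, symbols per bin), with red lines at 7 genes; the heights of the red lines carry no value. SNAI1 (93.8 FPKM) and CDH1 (84.3 FPKM) lie close together in the upper part of the distribution, VIM (2.12 FPKM) lies below the median of 4.79 FPKM, and the bin at the left end includes the 3115 symbols listed at 0.

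CDH1, the gene of E-cadherin and a classical target of repression by Snail, stood at 84.3 FPKM, 39.7-fold above the intermediate filament gene VIM (2.12 FPKM) and 13.8-fold above the N-cadherin gene CDH2 (6.12 FPKM). Of the 17 epithelial junction and polarity genes, 15 were at 1 FPKM or more and 10 at 10 FPKM or more. The median was 19.2 FPKM, at the 96.7th percentile, within the range of random lists (86.2nd with symbols under 1 FPKM left out). P-cadherin (CDH3) stood at 138.5 FPKM. The highest value, 262 FPKM for the tight junction gene CLDN7, was identical to that of the adjacent GABARAP, and the 103.7 FPKM of F11R was identical to that of TSTD1, so neither can be assigned to one gene. CLDN3 was listed at 0. All 10 desmosome genes were at 1 FPKM or more, with a median of 42.3 FPKM at the 99.7th percentile. They ranged from the plakophilin gene PKP1 at 6.96 FPKM through DSP (101 FPKM) and PERP (301 FPKM) to the plakoglobin gene JUP at 787.6 FPKM. All 9 hemidesmosome and laminin-332 genes were at 10 FPKM or more, with a median of 59.9 FPKM at the 99.9th percentile. ITGB4, the integrin subunit of hemidesmosomes, reached 130.5 FPKM, PLEC 69.5 FPKM and LAMB3 68.4 FPKM, and LAMA3 was lowest at 12.9 FPKM. Among 15 epithelial regulators the median was 37.5 FPKM, at the 99.9th percentile (13 at 1 FPKM or more). KLF5 stood at 156 FPKM and GRHL3 at 0.314 FPKM. The values of SPINT2 (379.6 FPKM, shared with C19orf33) and OVOL2 (148 FPKM, shared with SNX5) again belong to pairs of genes. With symbols under 1 FPKM left out of lists and background, desmosome genes (96.3rd percentile) and epithelial regulators (96.8th) lay within the range of random lists, and hemidesmosome genes stayed above it.

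KRT8 was at 1846 FPKM, KRT18 at 511.8 FPKM and KRT19 at 322 FPKM, and the median of the 4 simple epithelial keratins was 417 FPKM, above all 10000 random lists. The basal keratin genes KRT5 (1491 FPKM), KRT14 (132 FPKM) and KRT15 (47.6 FPKM) led the 7 measured basal and stress keratins, whose median of 32.3 FPKM lay at the 96.9th percentile, within the range of random lists (92.3rd with symbols under 1 FPKM left out). KRT6C was lowest at 0.0463 FPKM, and reads of the KRT6 copies are hard to separate. Squamous differentiation genes were low. Of 18 genes, 11 were under 1 FPKM and 8 were listed at 0, LOR among them, the gene of the cornified-envelope protein loricrin. The median was 0.0593 FPKM, at the 0.650th percentile and below random lists. The highest members were KRT13 (30.7 FPKM), CSTA (20.3 FPKM) and TGM1 (9.82 FPKM). The 7 members at 1 FPKM or more lay at the 11.9th percentile when symbols under 1 FPKM were left out.

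Mesenchymal genes were uneven. Their median of 7.98 FPKM over 14 genes lay at the 69.1st percentile, within the range of random lists, and 12 of the 14 were at 1 FPKM or more. These 12 lay at the 17.15th percentile of lists drawn from symbols at 1 FPKM or more, so the side of the middle on which the list lies depends on this setting. The upper end was held by LGALS1, the galectin-1 gene, at 2397 FPKM, by the actin-binding gene CALD1 at 105 FPKM and by TPM2 at 79.7 FPKM. Fibronectin (FN1) stood at 11.95 FPKM, and the smooth-muscle gene CNN1 was listed at 0. Fibrillar collagen and fibroblast genes lay below random lists, with a median of 0.0369 FPKM at the 0.720th percentile and 10 of 15 genes under 1 FPKM. COL6A2 was at 7.06 FPKM and COL6A1 at 6.42 FPKM, and POSTN was listed at 0. The 38.1 FPKM given for PDGFRA was identical to the value of the neighbouring FIP1L1 and cannot be assigned to the receptor gene. When symbols under 1 FPKM were left out, the list lay at the 10.5th percentile.

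Among matrix proteases and inhibitors, 14 of 15 were at 1 FPKM or more. The urokinase gene PLAU was highest at 189 FPKM, followed by the membrane-bound metalloproteinase gene MMP14 at 86.6 FPKM and the collagenase gene MMP13 at 43.2 FPKM, and MMP9 was lowest at 0.883 FPKM. Their median was 17.8 FPKM, at the 94.6th percentile, and at the 58.5th when symbols under 1 FPKM were left out, both within the range of random lists. Of 16 cytokine and chemokine genes, 14 were at 1 FPKM or more, led by CXCL1 (149 FPKM), the interleukin-8 gene IL8 (129 FPKM) and IL1B (85.0 FPKM), with CXCL5 lowest at 0.118 FPKM. Their median of 12.2 FPKM lay at the 87.1st percentile, and at the 41.65th when symbols under 1 FPKM were left out, within the range of random lists in both cases. In the TGF-beta pathway, SMAD3 (86.1 FPKM), TGFB1 (44.9 FPKM) and the TGF-beta-induced matrix gene TGFBI (41.4 FPKM) were highest. SMAD4, the gene of the common mediator of TGF-beta signalling, was listed at 0. The median of these 14 genes was 5.63 FPKM, at the 52.7th percentile (77.2nd with symbols under 1 FPKM left out).

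**Figure D2:**
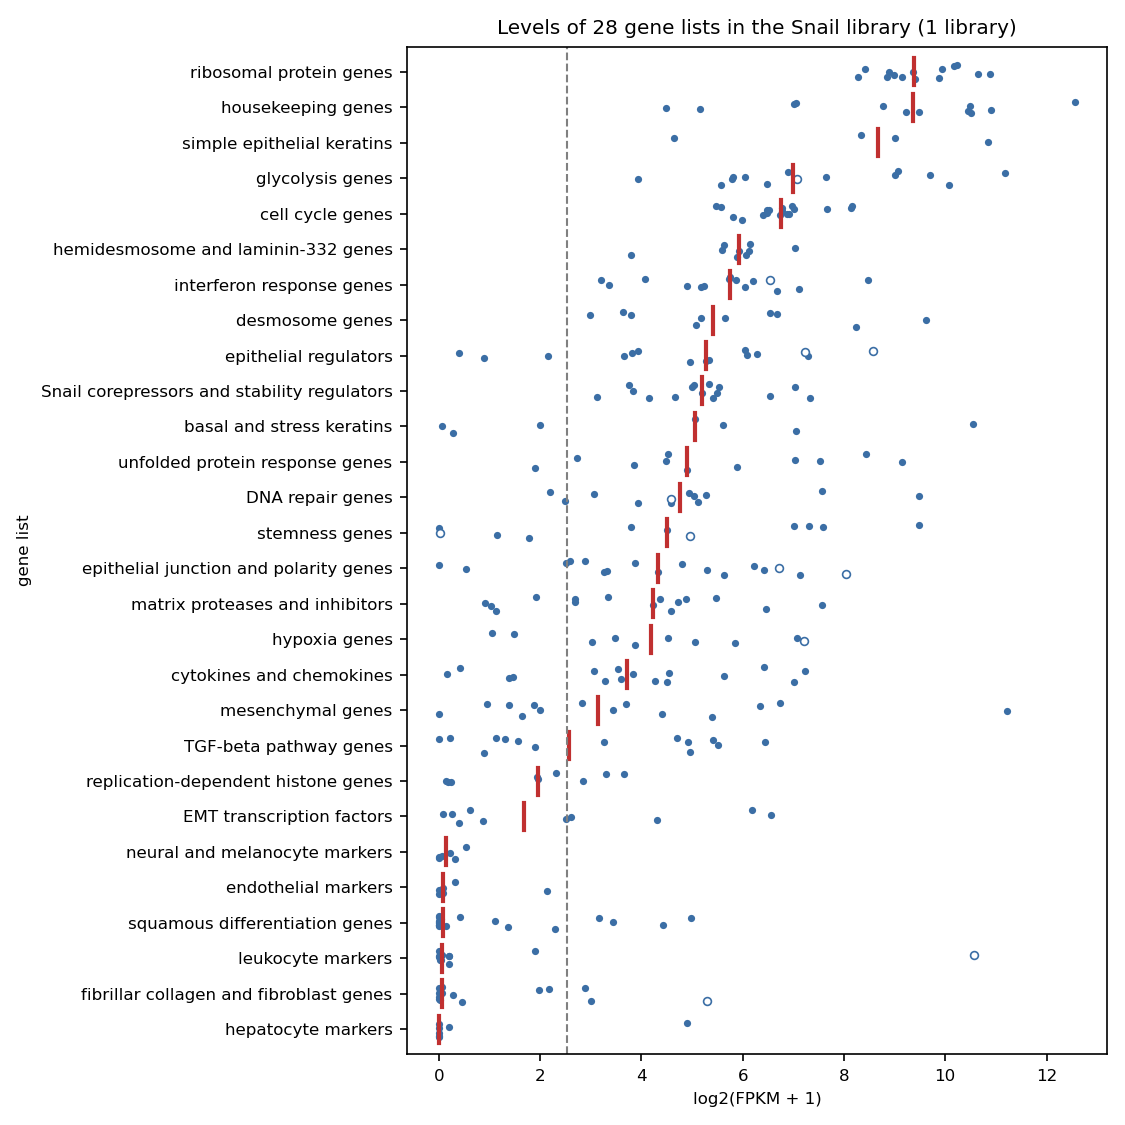
Levels of the genes in 28 lists, 1 point per gene, as log2(FPKM + 1) in the Snail library, with lists ordered by their median (red bar). Open points are genes whose value is identical to that of a neighbouring gene, and the dashed line is the median of all symbols (4.79 FPKM). Desmosome and simple keratin genes lie to the right of the dashed line, whereas squamous differentiation and fibrillar collagen genes are mostly at its left; the open point far to the right among leukocyte markers is CD68.

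Genes of proteins that act with Snail or on its stability were expressed. All 15 Snail corepressors and stability regulators were at 1 FPKM or more, with a median of 35.7 FPKM at the 99.8th percentile. The casein kinase gene CSNK1E (159 FPKM) and the histone deacetylase genes HDAC1 (129.7 FPKM) and HDAC2 (91.4 FPKM) were highest, and LATS2 was lowest at 7.70 FPKM. Against a background without symbols under 1 FPKM, the list lay at the 96.3rd percentile, within the range of random lists. Of 11 stemness genes, 9 were at 1 FPKM or more, with a median of 21.6 FPKM at the 95.5th percentile (85.9th with symbols under 1 FPKM left out). The retinaldehyde dehydrogenase gene ALDH1A3 was at 714 FPKM, CD44 at 190.5 FPKM and MYC at 157 FPKM, and the pluripotency gene NANOG was listed at 0.

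Cell cycle and glycolysis genes were high. Each of the 18 cell cycle genes exceeded 10 FPKM, from CCNA2 at 43.2 FPKM to CDK1 at 287 FPKM, with CCNB1 at 281 FPKM and MCM7 at 202 FPKM. Their median of 107 FPKM lay above all 10000 random lists. The 14 measured glycolysis genes had a median of 126 FPKM, also above all of them, led by GAPDH (2306 FPKM), ENO1 (1076 FPKM) and LDHA (835 FPKM), with HK2 lowest at 14.2 FPKM. The 10 hypoxia genes lay within the range of random lists (median 17.8 FPKM, 91.8th percentile, or 51.3rd with symbols under 1 FPKM left out). VEGFA was at 56.6 FPKM and NDRG1 at 133 FPKM, and the carbonic anhydrase gene CA9 was lowest at 1.07 FPKM. Of the 146 FPKM summed for HIF1A, 145 FPKM came from a row identical in value to SNAPC1, so this level cannot be assigned to HIF1A. The 15 interferon response genes were all at 1 FPKM or more, with a median of 52.5 FPKM at the 99.98th percentile. IFI27 was at 357 FPKM, IFI44 at 138 FPKM and OAS3 at 101 FPKM, and IRF7 was lowest at 8.17 FPKM. The unfolded protein response list had a median of 28.8 FPKM at the 98.4th percentile. It ranged from DDIT3 (2.72 FPKM) through the chaperone gene HSPA5 (184 FPKM) and ATF4 (344 FPKM) to HSP90B1 (562 FPKM). DNA repair genes had a median of 26.3 FPKM at the 98.1st percentile, with the Ku genes XRCC6 (711.5 FPKM) and XRCC5 (187 FPKM) above BRCA1 (37.7 FPKM) and ERCC4 (3.59 FPKM). With symbols under 1 FPKM left out, the unfolded protein response list (85.9th percentile) and the DNA repair list (82.0th) lay within the range of random lists.

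The 10 most abundant genes were EEF1A1 (6065 FPKM), NPM1 (4881 FPKM), ACTG1 (4389.8 FPKM), RPSA (3104 FPKM), RPL39 (3091 FPKM), FTH1 (2895 FPKM), PABPC1 (2879 FPKM), CTTN (2734 FPKM), LGALS1 and GAPDH. Together they held 6.31% of the summed FPKM. Most of them encode translation factors, ribosomal proteins or other housekeeping products. CTTN encodes cortactin, an actin-binding protein of invadopodia. The 12 housekeeping genes (median 657.5 FPKM) and the 14 ribosomal protein genes (median 666 FPKM) both lay above all 10000 random lists. Among the former ACTB reached 1905 FPKM, YWHAZ 1454 FPKM and GUSB 21.5 FPKM, and among the latter RPS2 was at 1889 FPKM and RPS4X, the lowest, at 309.5 FPKM. Replication-dependent histone genes, whose transcripts typically but not always lack poly(A) tails, had a median of 2.89 FPKM, at the 38.7th percentile. The list lay at the 3.19th when symbols under 1 FPKM were left out. HIST1H2BK was highest at 11.5 FPKM and HIST1H1E lowest at 0.106 FPKM.

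Markers of other cell types were mostly low. Of 11 leukocyte markers, 9 were under 1 FPKM, and their median of 0.0386 FPKM lay at the 1.85th percentile, below random lists. CD14 was at 2.75 FPKM, NKG7 at 0.156 FPKM, and CD3E was listed at 0. CD68 carried 1508 FPKM, a value identical to that of EIF4A1, SENP3 and SNORA67 in adjacent rows. The 7 hepatocyte markers also lay below random lists (1.065th percentile), with ALB at 0.155 FPKM, APOA1 listed at 0 and SERPINA1 at 28.8 FPKM. The 6 measured endothelial markers lay at the 4.38th percentile, within the range of random lists (13.9th with symbols under 1 FPKM left out), with CDH5 at 3.38 FPKM and VWF at 0.242 FPKM. The 6 measured neural and melanocyte markers lay at the 5.71st percentile, also within it, with MAP2 highest at 0.441 FPKM. With symbols under 1 FPKM left out, 2 leukocyte markers and 1 hepatocyte marker remained, and neither list lay below random lists (93.2nd and 65.9th percentiles).

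The neighbours of SMAD4 and CTTN on chromosomes 18 and 11 were then read in gene order. Among genes with a value, SMAD4 lay in a stretch of 6 consecutive genes listed at 0, comprising MAPK4, MRO, ME2, ELAC1, SMAD4 and MEX3C and involving both strands. The flanking SKA1 stood at 9.48 FPKM on one side, and on the other side DCC was at 0.00496 FPKM and MBD2 at 27.4 FPKM. Around CTTN, the values were 386 FPKM for the cyclin D1 gene CCND1, 53.6 FPKM for ANO1, 93.7 FPKM for FADD and 596 FPKM for PPFIA1. The fibroblast growth factor genes in the same interval were low, FGF3 at 2.82 FPKM, FGF19 at 0.647 FPKM and FGF4 at 0.139 FPKM.

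**Figure D3:**
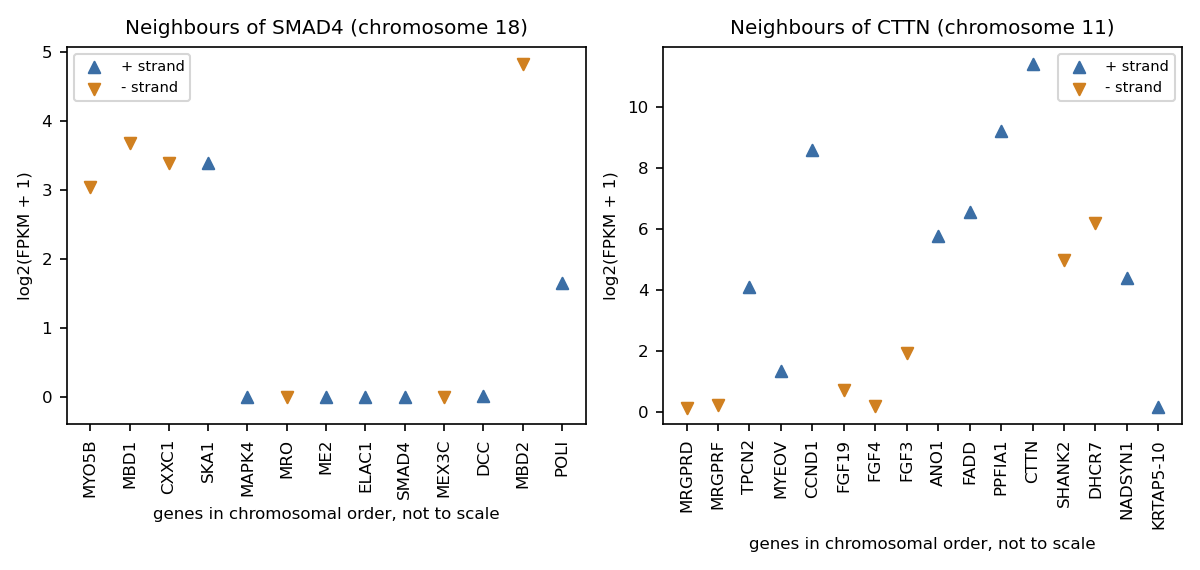
Levels, as log2(FPKM + 1), of the genes around SMAD4 (left) and around CTTN (right) in chromosomal order, with triangles pointing up for the + strand and down for the - strand. MAPK4 to MEX3C lie at 0 on both strands, between SKA1 (9.48 FPKM) and MBD2 (27.4 FPKM); CCND1, PPFIA1 and CTTN are the highest points of the right panel.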

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

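No setting changes the main limit: with 1 library of unknown depth, no value has a replicate error, and a level near 0 cannot be separated from absence. The detected count of 10923 symbols stayed within 1.5 times under each alternative run, from 8724 at 5 FPKM to 13000 at 0.1 FPKM, and was 11466 after rescaling to a sum of 1000000. Pseudocounts of 0.1 and 0.5 and keeping the highest row left the 12 lists above and the 4 below random lists in place. A pseudocount hardly moves the rank of a median by construction, and 34 repeated symbols have more than 1 nonzero row. With symbols under 1 FPKM left out of lists and background, 7 of the 12 remained above and 0 lists lay below, since this setting removes the low members of lists and raises the background. The lists no longer above were epithelial regulators (96.8th percentile), desmosome genes (96.3), Snail corepressors and stability regulators (96.3), unfolded protein response (85.9) and DNA repair (82.0). Of the 4 lists below, squamous differentiation (11.9) and fibrillar collagen and fibroblast genes (10.5) came to lie within. Lists within random lists before and after also moved, among them EMT transcription factors (32.0 to 55.1), mesenchymal (69.1 to 17.15), replication-dependent histone (38.7 to 3.19), cytokine and chemokine (87.1 to 41.65), matrix protease (94.6 to 58.5) and hypoxia genes (91.8 to 51.3). In all, 20 of the 27 lists left moved by more than the counting error of the random draws, and 2 further lists called below crossed the middle of the random lists. Leukocyte markers moved to the 93.2nd percentile, on CD14 and the shared CD68 value alone, and hepatocyte markers to the 65.9th, on SERPINA1 alone. Leaving out symbols with a shared value, an alternative chosen after seeing the data, gave 13 lists above, basal and stress keratins being added at the 97.7th percentile. Under it 16 of the 28 lists moved by more than the counting error, in both directions. Epithelial junction and polarity genes fell from the 96.7th to the 92.0th percentile and hypoxia genes from the 91.8th to the 86.2nd. The 10 highest genes held 6.50% of the sum without ribosomal protein, histone and mitochondrial genes and 6.84% with each shared value counted once (also chosen after seeing the data), against 6.31%. Among 119 named genes, keeping the highest row moved CDH3 by more than 1%, to 130.9 FPKM. Leaving out rows without a symbol could not be run, since every row has one, and the alternatives for fold changes were not run, as no control values were analysed here.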

Other observations

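A few further genes, chosen after their values were seen and not as a group, are given with their levels. The receptor gene EGFR stood at 98.6 FPKM, a level higher than 93.9% of all symbols, ERBB2 at 83.3 FPKM and the hepatocyte growth factor receptor gene MET at 63.8 FPKM. The 300.8 FPKM of ERBB3 was identical to that of the adjacent PA2G4 and cannot be assigned to the receptor. CDKN2A at 15.96 FPKM, NOTCH1 at 15.8 FPKM and FAT1 at 11.7 FPKM were lower but above 10 FPKM. The lipid kinase gene PIK3CA stood at 8.78 FPKM.

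All tests below were chosen after the value that prompted them was seen, except the reading of the strand opposite to SMAD4, which was fixed before those genes were looked at.

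SMAD4 and its row neighbours MAPK4, ME2 and ELAC1, which lie on one strand, were listed at 0. A candidate explanation is loss of this segment of chromosome 18 in the cells, which predicts that a gene of the opposite strand inside the segment is also near 0. MRO, the opposite-strand gene between MAPK4 and SMAD4, was at 0, so the highest FPKM between the outermost genes was 0, and MEX3C, next to SMAD4 on the opposite strand, was at 0 too. MRO is the single gene inside that prediction and may be silent in these cells anyway, and MEX3C lies outside it, so loss of the segment stays open. Estimates failing at scattered genes stay open too. Of 109 genes of the POLR2, NDUF, ATP5, SF3 and PSM families, 1 (PSMA8) was listed at 0, or 0.917% (exact 95% interval 0.0232% to 5.01%). The interval reached just past the limit set for this test, and its upper end rests on PSMA8 alone. None of the POLR2, NDUF, ATP5 and SF3 genes was listed at 0. AHNAK, a gene abundant in many epithelial cells, was also listed at 0. It was picked after its value was seen, so it gives no rate of failure. Silencing of the stretch or a gap in the table limited to it was not tested.

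CD68, a macrophage marker, carried 1508 FPKM in a carcinoma line. Leukocytes in the culture are argued against. The highest of the other leukocyte markers, CD14, reached 2.75 FPKM, under 1% of the CD68 value. That value is a weak yardstick, since it may not belong to CD68, but 9 of the 11 leukocyte markers were under 1 FPKM. The value is consistent with 1 value shared by neighbouring genes, since 4 symbols (CD68, EIF4A1, SENP3 and SNORA67) held it to the last digit. EIF4A1 encodes a translation initiation factor that dividing cells use widely, and a fold change of CD68 computed from such values could be that of EIF4A1. The same caution applies to PDGFRA beside FIP1L1, CLDN7 beside GABARAP and OVOL2 beside SNX5. No explanation tied to the Snail construct was tested.

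CTTN was the 8th most abundant gene, and PPFIA1 (596 FPKM), CCND1 (386 FPKM) and ORAOV1 (209 FPKM) lie close to it. This chromosome region is often amplified in head-and-neck carcinoma, and a gain of the segment is a possible explanation. The 5 placed genes from CCND1 to CTTN at 1 FPKM or more, CTTN left out, had a median of 93.7 FPKM, above 97.6% of 10190 windows of as many consecutive expressed genes. Without CCND1 or without PPFIA1 this fell to 93.6%. With ORAOV1 added through its older symbol it was 99.4%, and leaving out each of these 6 genes in turn gave 97.53% to 99.61%. The interval was chosen after its values were seen, which favours a high rank among windows that were not chosen. Just outside it, MYEOV (1.52 FPKM) and TPCN2 (16.3 FPKM) lay on the CCND1 side. On the CTTN side lay SHANK2 (30.7 FPKM) and DHCR7 (72.2 FPKM). A value shared by neighbouring genes is argued against, since 0 values above 0 were repeated in the interval. Whether the segment is gained stays open, since a highly expressed neighbourhood without extra copies was not excluded.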
